A study of Mus musculus with 7 samples.

How the data were processed

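Small RNA libraries were made from ovarian tissue of 8-week-old ICR mice. Per the labels 4 libraries, titled PCOS and called PNA here, came from offspring of pregnancies exposed to dihydrotestosterone (DHT, an androgen that is not converted to oestrogen), and 3 are controls without treatment. The labels number the PNA libraries 1, 2, 3 and 4 and the control libraries 2, 3 and 6, and these numbers name the libraries here. The labels do not state that each library came from a separate animal, so p-values measure the spread between these libraries, which may be partly technical.

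The authors deposited raw read counts per mature mouse miRNA, 1017 rows in all, each with a miRNA name and none repeated. Beside them the deposited table gives RPM, which per the file headers and the values is the count divided by the library's total over these rows, put on the RPM scale. The submitters' processing notes name the aligner Bowtie2 version 2.1.0 and the genome build mm10. Adapter trimming, the miRNA annotation, the counting tool, its use of strand and its treatment of reads that align to several loci are not given in the sources used here. RNA-seq of the same tissue is part of the study's aim and is not analysed here. No column of the table was left unmatched to a library.

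Counts were analysed as deposited. Rows were kept by the filterByExpr function of edgeR 4.0.16 (minimum count 10, minimum total 15), which left 368 rows, and these held 99.3% of counts in the library where they held least. Libraries were scaled by TMM, and levels are given as CPM on TMM-scaled totals with the SD between libraries. The 2 groups were compared by edgeR's two-sided quasi-likelihood F test with Benjamini-Hochberg adjustment at 0.05, in R 4.3.3. Every adjusted p of a single miRNA is from that test unless another tool is named. Fold changes are log2 values of PNA over control, so a negative value is a lower level in PNA.

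A set of 24 miRNA lists was written before the data were examined, covering families, clusters, hormone response, PCOS and markers of other cell types that a dissected ovary can hold. Lists with at least 3 tested rows were compared by camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 19 lists. Camera with a correlation estimated from the data and the fry test stand beside it. The 2 camera settings differ by more than the correlation value, so a lost call is not by itself a sign of correlated members. Comparisons of 1 value per library used an exact two-sided permutation test of the difference of means over all 35 splits of the 7 libraries, for which the smallest possible p is 0.0286.

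The miRNAs named were chosen by a rule fixed before the data were examined. It takes the 10 largest changes in each direction past the threshold at a mean of at least 10 RPM. Where fewer than 10 pass, it also takes the 10 rows with the smallest unadjusted p at that mean. It adds the 10 most abundant rows and, for each list, 2 to 4 of its members with the highest mean level. Other rows named, such as those on opposite strands of a hairpin and those of miRNAs with several loci, were chosen after their values were seen. Coordinates and host genes are from GENCODE M21 on GRCm38, the assembly also called mm10, and 973 of the 1017 rows (95.7%) matched a hairpin gene by name.

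Total counts over the listed miRNAs ran from 2609770 in control replicate 6 to 8403168 in PNA replicate 4. A level of 3 counts, taken as the floor, is 1.15 RPM in the first and 0.357 RPM in the second, for counting error only. The edgeR step was tested on simulated data with the means, library sizes and common dispersion of these 7 libraries, with 200 of the 1017 rows changed in each of 20 simulations. Of the tested rows simulated for PNA against control, it called 17.0% of those changed 2-fold, 79.0% of those changed 4-fold and 98.9% of those changed 8-fold, and 0.566% of unchanged rows. In 20 simulations with no change it called 1 row in all. Every simulated row had the same dispersion, so the rates for changed rows may be too high for miRNAs that vary more between libraries. Camera called a planted list of 30 rows raised 2-fold in 20 of 20 simulations and an unchanged list in 1. Rows were simulated independently of each other, so this does not cover lists whose members vary together. In the data the estimated correlation was 0.607 for the list of the Dlk1-Dio3 imprinted cluster. The comparison with matched random lists found a list shifted between libraries in 20 of 20 simulations, and placed an unshifted list above its 95th percentile in 3.

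Alternatives planned before the data were examined were DESeq2 size factors, total counts and upper quartile factors for scaling, the DESeq2 1.42.0 Wald test, limma-voom, no filter, a mean of at least 10 RPM, a threshold of 0.1, prior counts of 0.5 and 5, the replicate number as a block, the top 5 and top 20 rows for shares, and each library left out in turn. Alternatives chosen after seeing the data were the removal of rows on the strand opposite to another hairpin, with and without the filter, of arms shared by several loci, and of miR-10b-5p. Leaving out libraries for the counts adjusted over a list alone was also added then, as were the 4 libraries of the block without it, and an estimated correlation joined to these, to the block, to a mean of at least 10 RPM and to the removal of control replicate 6. Hairpin overlaps and plots were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.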

Results

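Mature miRNAs were counted in ovaries of adult mice that had been exposed to an androgen before birth (PNA, n = 4 libraries) and in untreated control ovaries (n = 3). Prenatal androgen exposure is used to model polycystic ovary syndrome (PCOS), and the study set out to find miRNAs of a regulatory network in such ovaries. Library totals were 5102039, 5225614 and 2609770 counts in control replicates 2, 3 and 6, and 6455585, 6694383, 4937268 and 8403168 in PNA replicates 1, 2, 3 and 4. Between 549 and 727 miRNAs were detected per library.

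The counts over the listed miRNAs were dominated by few miRNAs in both groups. Some miRNAs with several loci had low counts or were not listed, such as miR-24-3p. The shares are therefore of the listed counts and may differ from those of the whole ovarian miRNA pool. miR-10b-5p, encoded in an intron of Hoxd3 (chromosome 2, 74726070 to 74726137, GRCm38), held 53.9% ± 5.56 of counts in PNA (SD, n = 4) and 51.6% ± 16.9 in control (SD, n = 3). Single libraries ran from 36.7% in control replicate 2 to 69.9% in control replicate 6. miR-143-3p, a miRNA abundant in smooth muscle and stroma (intergenic, chromosome 18, 61649196 to 61649258), held 13.9% ± 2.46 and 14.5% ± 4.78. miR-148a-3p followed with 5.80% ± 0.647 and 7.0% ± 3.38, miR-22-3p with 3.16% ± 1.45 and 3.59% ± 3.29, and miR-30a-5p with 2.69% ± 1.05 and 2.75% ± 0.843. miR-27b-3p, miR-21a-5p, miR-30d-5p, miR-191-5p and miR-10a-5p each held between 1.17% and 2.71% on average in either group. The 10 together took 88.1% ± 1.43 of counts in PNA and 88.8% ± 3.06 in control, a difference of -0.68 percentage points that was smaller than the spread between libraries (exact permutation p = 0.714, adjusted 0.83 over 4 such tests). The share of miR-10b-5p alone did not separate the groups either (exact permutation p = 0.83, adjusted 0.83).

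No miRNA passed the test between PNA and control ovaries. By edgeR and limma-voom, 0 of the 368 miRNAs tested had an adjusted p under 0.05, and the smallest adjusted p by edgeR was 0.656. DESeq2, run with its own filter on all rows with a read instead of the 368, also gave 0. At an unadjusted p under 0.05 edgeR counted 13 miRNAs, 4 higher and 9 lower in PNA, where chance alone gives 18.4. That count was 23 by DESeq2, to whose different set of rows the 18.4 does not apply, 10 by limma-voom and 8 with total counts. With 1 library left out it ran from 9 to 35 (35 without PNA replicate 1, 31 without control replicate 2, 20 without PNA replicate 3). The groups did not overlap for 15 of the 368 miRNAs, a smaller share than the 5.71% expected by chance. The lack of overlap given for single miRNAs below is thus not beyond chance. The biological coefficient of variation was 0.455 and the median SE of a log2 fold change 0.49.

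The values below belong to the 10 miRNAs with the smallest unadjusted p, none of which passed the threshold. The erythroid miRNAs miR-486a-5p and miR-451a had higher levels in every PNA library than in any control. miR-486a-5p (intron of Ank1, chromosome 8, 23142555 to 23142682) stood at 55.0 ± 26.5 CPM in PNA (SD, n = 4) and 18.5 ± 3.04 in control (SD, n = 3), a log2 fold change of 1.57 ± 0.47 (SE). Both miR-486a-5p and miR-486b-5p hold a run of at least 20 nt found in another hairpin, so their reads may not be separable. Control replicate 6 had 34 reads for miR-486a-5p and 147 for miR-486b-5p, against 1948 and 685 over the other libraries together. In control replicate 6 miR-486b-5p alone stood higher than the PNA mean of miR-486a-5p. The lack of overlap thus holds for miR-486a-5p as listed and may be lost with both joined, which was not tested. miR-451a (intergenic, chromosome 11, 78073170 to 78073241) stood at 253 ± 130 and 95.7 ± 29.3 CPM, a log2 fold change of 1.40 ± 0.43. miR-127-3p, from the imprinted Dlk1-Dio3 region and antisense to an exon of Rtl1 (chromosome 12, 109592846 to 109592915), stood at 3996 ± 2213 and 1770 ± 181 CPM, with all 4 PNA libraries above all 3 controls (log2 fold change 1.17 ± 0.41). All 3 had an adjusted p of 0.656.

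Lower mean levels in PNA were seen for the other 7. miR-155-5p, a miRNA of activated immune cells (exon of Mir155hg, chromosome 16, 84714140 to 84714204), stood at 12 ± 2.89 CPM in PNA and 26.8 ± 8.35 in control (log2 fold change -1.15 ± 0.41, SE), and miR-3068-3p (intron of Alkbh1, chromosome 12, 87437679 to 87437757) at 19.0 ± 2.75 and 42.0 ± 17.2 CPM (-1.13 ± 0.40). For both, every PNA library lay below every control. miR-200a-3p, an epithelial miRNA (chromosome 4, 156054896 to 156054985, intron of Ttll10), had the smallest unadjusted p, with 26 ± 17.3 and 275 ± 396 CPM (-3.40 ± 0.89). Its 3 control values were 51.0, 41.9 and 733 CPM in replicates 2, 3 and 6. Without control replicate 6 its log2 fold change was -0.81. miR-503-5p (chromosome X, 53053984 to 53054054) was likewise at 442 CPM in control replicate 6 against 17.7 and 21.2 in the other controls (-2.24 ± 1.01), and without that library its log2 fold change was 0.77. miR-130a-3p (-1.36 ± 0.43), miR-184-3p (-2.14 ± 0.70) and miR-677-5p (-1.65 ± 0.63) completed the 10.

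**Figure D1:**
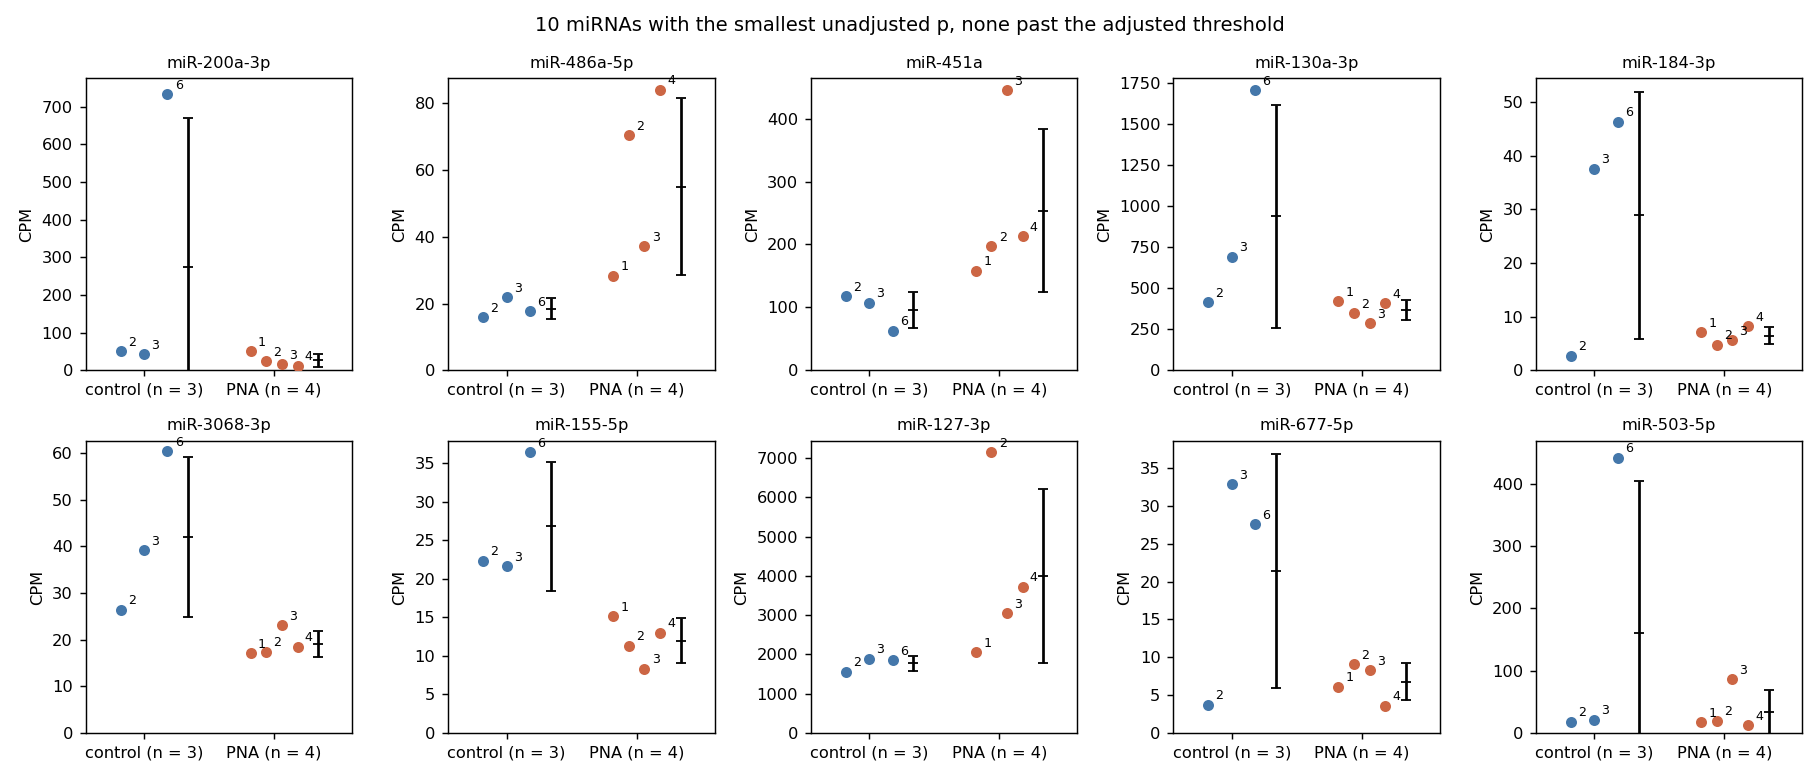
Level in CPM (linear axis from 0) of the 10 miRNAs with the smallest unadjusted p in each control (n = 3) and PNA (n = 4) library; points are libraries with their replicate numbers, and the black mark and bar are the mean and SD, truncated at 0. Control replicate 6 reaches 733 CPM for miR-200a-3p, whereas miR-486a-5p, miR-451a and miR-127-3p are higher in all 4 PNA libraries than in any control. The level of miR-486a-5p is shown without the reads assigned to miR-486b-5p, from which its own may not be separable.

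Leaving out control replicate 2 brought 1 miRNA past the threshold, miR-184-3p (log2 fold change -2.73, adjusted p = 0.0167), which stood at 2.70 CPM in that library and at 37.6 and 46.3 in the other controls. Without the filter on low counts 15 miRNAs passed by edgeR, 11 of which had reads in control replicate 6 alone. The others were miR-200a-3p (adjusted p = 9.84e-11), miR-503-5p (adjusted p = 0.000185), miR-184-3p (adjusted p = 0.00598) and miR-5100 (adjusted p = 0.000248).

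Of the 24 lists, 19 had enough tested members, and camera with the preset correlation called 5, of which 2 were higher and 3 lower in PNA. None of the 5 calls held with an estimated correlation, and fry called 0. The miRNAs of the Dlk1-Dio3 imprinted cluster, processed from maternally expressed transcripts of chromosome 12, were higher in PNA as a list. Of 42 tested members 38 had a higher and 4 a lower mean, and the mean log2 fold change was 0.64 (median 0.66; adjusted p = 8.56e-08 by camera, adjusted p = 0.470 with an estimated correlation). No member passed, neither over all miRNAs (0) nor adjusted over the list alone (0). After miR-127-3p its most abundant members were miR-411-5p, at 785 ± 518 CPM in PNA (SD, n = 4) and 523 ± 186 in control (SD, n = 3), miR-541-5p, at 448 ± 349 and 299 ± 221, and miR-434-3p, at 247 ± 163 and 149 ± 108. The list's mean level did not separate the groups, at 3.50 ± 0.82 log2 CPM in PNA and 2.86 ± 0.50 in control (exact permutation p = 0.229), and was lowest in control replicate 3 (2.28) and PNA replicate 1 (2.35).

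The list of erythroid miRNAs was higher in PNA by camera (adjusted p = 0.0184). Its mean log2 fold change was 0.67 over 6 members, 4 higher and 2 lower. By camera with an estimated correlation the adjusted p was 0.446. The estimated correlation was -0.0116, below the preset 0.01, yet the unadjusted camera p rose from 0.00309 to 0.0284. Correlation between members thus does not account for the loss of this call. miR-451a and miR-486a-5p passed when adjusted over the list alone (2 members, smallest adjusted p = 0.0209), and 0 passed over all miRNAs. Over the list alone none passed without control replicate 2, control replicate 6 or PNA replicate 2 (smallest adjusted p = 0.0650, 0.0711 and 0.0508). Only 1 passed without PNA replicate 3 (miR-486a-5p) or PNA replicate 4 (miR-451a). As given above, reads of miR-486a-5p and miR-486b-5p may not be separable, so the level of each may depend on how these were assigned. The 2 lower members, miR-486a-3p (log2 fold change -1.07 ± 1.03, SE) and miR-486b-5p (-0.60 ± 0.75), lie on opposite strands of 1 locus and each stood at 76.5 CPM in control replicate 6. By limma-voom, and without that library, the log2 fold changes of both were above 0. The summed level of the erythroid list was 8.4 ± 0.55 log2 CPM in PNA (SD, n = 4) and 7.55 ± 0.42 in control (SD, n = 3), a difference of 0.86 that did not pass (exact permutation p = 0.114, adjusted 0.457).

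The leukocyte list was lower in PNA by camera, with a mean log2 fold change of -0.43 over 7 members, 2 higher and 5 lower (adjusted p = 0.0184; adjusted p = 0.470 with an estimated correlation). Its most abundant members were miR-142a-5p, at 645 ± 468 CPM in PNA (SD, n = 4) and 516 ± 250 in control (SD, n = 3), and miR-146a-5p, at 538 ± 420 and 625 ± 254. They were followed by miR-342-3p (103 ± 51.7 and 70.6 ± 16.6) and miR-150-5p (35.5 ± 10.9 and 45 ± 10.7). No member passed over all miRNAs (0) or adjusted over the list alone (0). The summed leukocyte level, in which miR-142a-5p and miR-146a-5p weigh most, was 10.2 ± 1.01 log2 CPM in PNA and 10.4 ± 0.31 in control (exact permutation p = 0.771, adjusted 0.83).

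The epithelial miR-200 family list was lower in PNA by camera, with a mean log2 fold change of -0.76 over 6 members, 2 higher and 4 lower (adjusted p = 0.0184; adjusted p = 0.470 with an estimated correlation). miR-200a-3p passed when adjusted over the list alone (1 member, adjusted p = 0.0140) and 0 passed over all miRNAs. Over the list alone it did not pass without control replicate 6, PNA replicate 2 or PNA replicate 3 (smallest adjusted p = 0.461, 0.0515 and 0.0781). Without PNA replicate 1 miR-200b-3p and miR-429-3p passed too (3 members). miR-429-3p stood at 24.6 ± 18.1 CPM in PNA (SD, n = 4) and 47.3 ± 10.8 in control (SD, n = 3), and miR-200b-3p at 24.1 ± 20.7 and 41.8 ± 10.9. miR-205-5p, another epithelial miRNA, stood at 102 ± 72.0 and 84.8 ± 54.6. miR-141-3p, of the miR-200 family itself, was not lower in PNA. It stood at 38.1, 9.41, 9.92 and 16.5 RPM in PNA replicates 1, 2, 3 and 4. In control replicates 2, 3 and 6 it stood at 5.10, 17.8 and 7.28 RPM. The family thus did not change in 1 direction. The miRNAs reported in PCOS were lower as a list, with 8 of 28 members higher and 20 lower and a mean log2 fold change of -0.19 (adjusted p = 0.0184; adjusted p = 0.446 with an estimated correlation), and 0 members passed over all miRNAs or adjusted over the list alone. Among them miR-21a-5p stood at 16741 ± 2994 and 21054 ± 4674 CPM, miR-27b-3p at 22129 ± 6012 and 27212 ± 4171, and miR-151-3p at 4274 ± 1483 and 3174 ± 1782.

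With 1 library left out, the lists called numbered 2 without control replicate 2 (Dlk1-Dio3 and miR-200), 1 without control replicate 3 and 1 without PNA replicate 3 (Dlk1-Dio3 in both), 4 without PNA replicate 4 (PCOS lost), and 6 without control replicate 6. Some losses came with mean log2 fold changes as large as before or larger, as for erythroid (0.70), leukocyte (-0.50) and PCOS (-0.24) miRNAs without control replicate 2 (adjusted p = 0.0905 for each) and the miR-200 family without control replicate 3 (-0.85, adjusted p = 0.0797). Others came with smaller ones, as for erythroid miRNAs without control replicate 3 (0.32, adjusted p = 0.177), leukocyte miRNAs without PNA replicate 3 (-0.23, adjusted p = 0.294) and PCOS miRNAs without PNA replicate 4 (-0.10, adjusted p = 0.103). Without control replicate 6 the miR-200 family was no longer called (-0.36, adjusted p = 0.112), and the gonad-enriched and smooth muscle lists were called instead (adjusted p = 0.0227 and 0.0456; adjusted p = 0.497 for both with an estimated correlation).

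**Figure D2:**
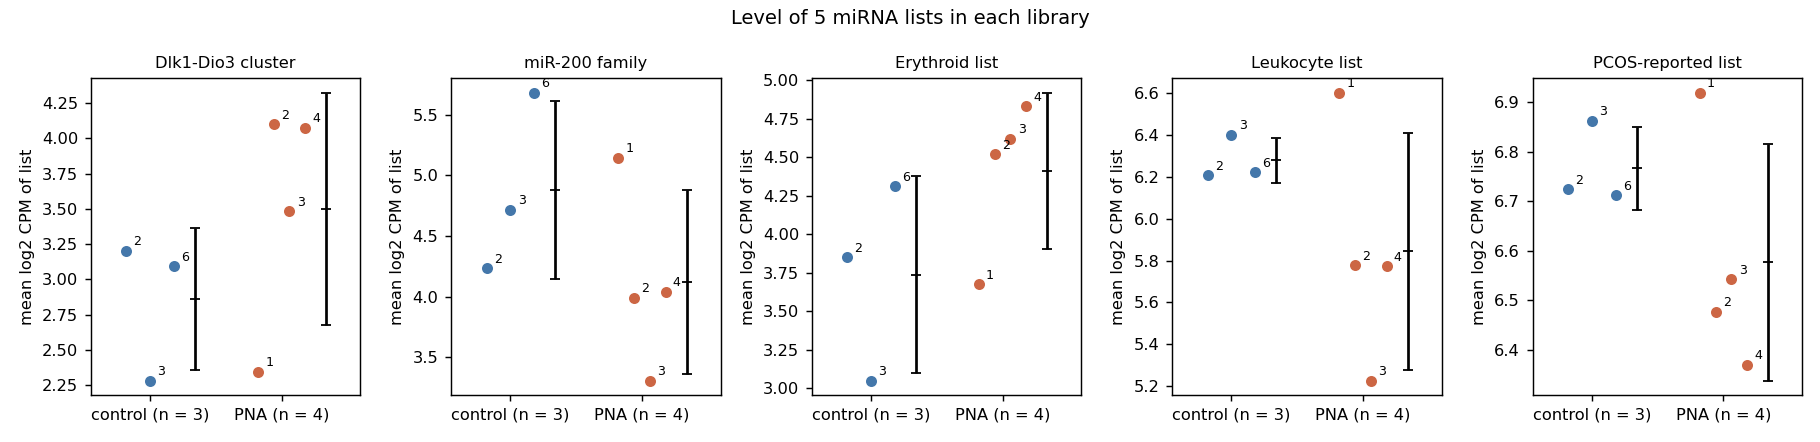
Mean log2 CPM over the tested members of the 5 lists called by camera with the preset correlation, in each control (n = 3) and PNA (n = 4) library; points are libraries with their replicate numbers, the black mark and bar are the mean and SD, and the vertical axes do not start at 0. The groups overlap in every panel, and PNA replicate 1 has the lowest PNA level of the Dlk1-Dio3 cluster (2.35).

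The other 14 lists tested did not pass. At a mean of at least 10 RPM camera also called the gonad-enriched list (adjusted p = 0.0371), the inflammation and hypoxia list and the miR-99, miR-100 and miR-125 group (adjusted p = 0.0468 for both). None of the 3 held there with an estimated correlation (adjusted p = 0.414 for each). Among lists of the gonad, the gonad-enriched miRNAs had 14 of 16 members higher in PNA (mean log2 fold change 0.23, 0.017 without control replicate 3, adjusted p = 0.102), with miR-351-5p at 8657 ± 3072 CPM in PNA (SD, n = 4) and 5713 ± 1129 in control (SD, n = 3), and miR-322-5p at 1678 ± 390 and 1163 ± 265. The list of gonadotropin and steroid hormone response had 8 members higher and 9 lower, a mean of -0.08, a median of 0.03 and camera on the lower side (adjusted p = 0.362). Its member miR-202-5p, known from the gonads, stood at 1430 ± 445 and 1426 ± 547 CPM. The androgen-responsive miRNAs had 10 members higher and 12 lower, with a mean of 0.02, a median of -0.08 and camera again on the lower side (adjusted p = 0.513), and included miR-148a-3p and miR-182-5p (4866 ± 2684 and 3537 ± 1752 CPM).

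Lists of other cell types and families gave similar results. All 4 smooth muscle members had lower means in PNA (mean log2 fold change -0.36, adjusted p = 0.102), among them miR-143-3p and miR-145a-5p (636 ± 222 CPM in PNA, SD, n = 4, and 810 ± 283 in control, SD, n = 3). The 4 are both arms of miR-143 and both arms of miR-145a, so they do not count as 4 independent miRNAs. The inflammation and hypoxia list had 6 of 8 members lower (-0.22, -0.033 without control replicate 3, adjusted p = 0.102), the miR-99, miR-100 and miR-125 group 8 of 10 higher (0.29, adjusted p = 0.178), and the let-7 family 7 of 9 lower (-0.14, adjusted p = 0.216). let-7i-5p stood at 3317 ± 616 and 4693 ± 1737 CPM, miR-125a-5p at 3780 ± 597 and 4009 ± 945, and miR-99b-5p at 2686 ± 397 and 2486 ± 1385. The 3 tested members of the miR-183, miR-96 and miR-182 cluster were higher on average (0.65, 0.13 without control replicate 6, adjusted p = 0.224), with miR-183-5p at 1087 ± 709 and 494 ± 478 CPM. The multiciliated epithelium list was written to mark the oviduct, but its 4 tested members were the arms of miR-34b and miR-34c alone. Its mean was -0.32 (-0.029 without control replicate 2, adjusted p = 0.224), with miR-34c-5p at 866 ± 278 and 1360 ± 833 CPM. These values alone do not measure oviduct content.

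The mean log2 fold change was -0.07 for the miR-29 and miR-30 families (adjusted p = 0.513), -0.10 for the HOX-embedded miR-10 and miR-196 (adjusted p = 0.513), 0.14 for the Sfmbt2 intron cluster (adjusted p = 0.632), 0.13 for the adipose list (adjusted p = 0.632) and -0.003 for the miR-17 to 92 clusters (adjusted p = 0.643). The means of the hormone response, miR-17 to 92, HOX-embedded and miR-29 and miR-30 lists changed sign with total counts as the only scaling, and that of the androgen-responsive list with DESeq2 size factors. miR-92a-3p of the miR-17 to 92 list stood at 2858 ± 716 and 2454 ± 34 CPM, miR-378a-3p of the adipose list at 1244 ± 343 and 1336 ± 159, and miR-669c-5p of the Sfmbt2 list at 3.60 ± 2.05 and 4.08 ± 0.93.

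The remaining 5 lists had fewer than 3 tested members and were not tested as lists. For the endothelium, miR-126a-5p, encoded in an exon of Egfl7 (chromosome 2, 26591357 to 26591429), stood at 15213 ± 7170 CPM in PNA (SD, n = 4) and 13098 ± 6196 in control (SD, n = 3), and miR-126a-3p at 740 ± 106 and 875 ± 167. In the liver list miR-192-5p stood at 2284 ± 1043 and 2085 ± 338 CPM, while miR-122-5p, the hepatocyte miRNA, did not exceed 0.77 RPM in any library. The most abundant neural member, miR-128-3p, stood at 6.61 ± 2.16 and 5.76 ± 1.90 CPM. Neither the oocyte and early embryo cluster miR-290 to miR-295, led by miR-295-3p at up to 1.57 RPM, nor the skeletal muscle list, led by miR-499-5p at up to 1.34 RPM, had a member that passed the filter on low counts. Only 3 of the 6 skeletal muscle members were listed, and miR-128-3p is encoded at 2 loci. Low values here thus do not show that such tissues were absent.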

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

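No test in this part was chosen after its result was seen. Of 107 values examined in the 4 PNA libraries (named miRNAs, list levels and single values), 6 had 1 library set apart from the other 3 by more than the 95% limit for the gap over the range, where chance marks about 1 in 20. The 3 controls were too few for this test. miR-200b-3p was highest in PNA replicate 1, at 5.79 log2 CPM against 3.87 in the nearest library (gap over range 0.939). In PNA replicate 3, miR-34b-3p stood at 6.31 against 4.81 (0.946) and miR-322-5p at 11.14 against 10.59 (0.830). miR-455-3p was highest in PNA replicate 4, at 6.77 against 5.59 (0.961), and miR-30e-5p lowest in PNA replicate 2, at 11.78 against 12.80 (0.884). PNA replicate 4, with the highest total count, had 727 miRNAs detected against 646 in the nearest library (0.920).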

How the results depend on the processing

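Settings named as removals of miRNAs, the 4 libraries without a block, and an estimated correlation joined to another setting were chosen after seeing the data; all others were planned. The count of 0 miRNAs held with DESeq2 size factors, total counts, upper quartile factors, DESeq2, limma-voom, a mean of at least 10 RPM, a threshold of 0.1, and without opposite-strand miRNAs, shared arms or miR-10b-5p. It was 15 with no filter and 5 with no filter and without the opposite-strand miRNAs that have coordinates in the reference (miR-203b-5p, without coordinates, is still among the 5), and 0 to 1 with a library left out. The 5 lists called were the same with DESeq2 size factors, total counts, both other prior counts and the 3 removals. With an estimated correlation 0 were called, and 0 by fry. With no filter 2 were called (Dlk1-Dio3 and leukocyte). Those lost were erythroid (mean log2 fold change 0.35, adjusted p = 0.0882 by camera), miR-200 (-0.54, adjusted p = 0.0516) and PCOS (-0.15, adjusted p = 0.0553). At a mean of at least 10 RPM 8 were called, and 0 there with an estimated correlation. The lists gained were gonad-enriched, inflammation and hypoxia, and the miR-99, miR-100 and miR-125 group. With a library left out 1 to 6 were called. The difference in the top 10 share was 0.0070 points for the top 5, 0.117 for the top 20, and -2.41 to 0.519 with a library left out; the leukocyte level difference then ran from -0.59 to 0.21. Except for the filters and the test itself, the cause was not tested. Total counts shifted the median log2 fold change of all miRNAs by 0.10 and upper quartile factors by -0.13, so small fold changes are relative to that choice.

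Replicate numbers 2 and 3 occur in both groups, and libraries sharing a number did not deviate together (correlations of deviations -0.12 and -0.16). With only those 4 libraries and no block, 0 miRNAs and 8 lists were called, and with the replicate number as a block 0 and 7. Both fits kept the 5 lists and also called the androgen-responsive list, lower in PNA (-0.28; adjusted p = 0.0155 by camera without the block and 0.0287 with it), and the gonad-enriched list, higher at 0.55 (adjusted p = 0.0155 and 0.0344). With an estimated correlation 0 lists were called in either fit (adjusted p = 0.632 and 0.865 for the androgen-responsive list, 0.434 and 0.646 for the gonad-enriched). The miR-29 and miR-30 families were called only without the block (adjusted p = 0.0331; adjusted p = 0.434 with an estimated correlation). The gained calls and nearly all sign changes against the 7 libraries thus came with the choice of libraries and not with the block. The log2 fold change without and with the block was 1.43 and 1.09 for miR-503-5p, 0.38 and 0.49 for miR-10b-5p, 0.14 and 0.14 for miR-25-3p, 0.16 and 0.10 for miR-669c-5p, 0.40 and 1.25 for miR-486a-3p, and 1.37 and 1.36 for miR-486b-5p. It was -0.69 and -0.81 for miR-142a-5p, -0.48 and -0.51 for miR-182-5p, -0.25 and -0.10 for miR-99b-5p, 0.073 and -0.0023 for miR-107-3p, and 0.074 and -0.091 for miR-342-3p. Of these, miR-342-3p had the sign of the 7 libraries without the block, and miR-107-3p had it with the block. For lists both fits gave 0.31 for miR-17 to 92, 0.073 for the HOX-embedded and -0.18 for the miR-183 cluster list, again of the opposite sign to the 7 libraries.

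None of the other values that changed sign passed the test. With total counts the log2 fold change was 0.056 for miR-10b-5p, 0.12 for miR-669c-5p, 0.025 for miR-378a-3p and 0.12 for miR-125a-5p, and for lists 0.12 (miR-17 to 92), 0.052 (hormone response), 0.024 (HOX-embedded) and 0.058 (miR-29 and miR-30). miR-202-5p was at -0.016 with DESeq2 size factors, -0.089 with upper quartile factors, -0.00048 without opposite-strand miRNAs and -0.014 without miR-10b-5p, and miR-99b-5p at -0.076 with upper quartile factors. The androgen-responsive list was at -0.0085 with DESeq2 size factors and -0.017 without miR-10b-5p. With limma-voom miR-22-3p was at 0.046, miR-486a-3p at 0.14 and miR-486b-5p at 0.40. At a mean of at least 10 RPM the miR-17 to 92 list was at 0.071 and the HOX-embedded list at 0.050.

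With each library left out in turn, log2 fold changes that changed sign ran from -3.29 to 0.77 for miR-503-5p, -0.53 to 0.33 for miR-10b-5p, -0.34 to 0.089 for miR-143-3p, -0.58 to 0.12 for miR-148a-3p, -0.47 to 0.47 for miR-22-3p, -0.60 to 0.22 for miR-30a-5p, -0.45 to 0.19 for miR-30d-5p, -0.30 to 0.032 for miR-25-3p, -0.28 to 0.21 for miR-202-5p and -0.43 to 0.13 for miR-669c-5p. They ran from -0.11 to 0.86 for miR-205-5p, -1.68 to 0.54 for miR-486a-3p, -1.15 to 1.34 for miR-486b-5p, -0.29 to 0.65 for miR-142a-5p, -0.70 to 0.096 for miR-146a-5p, -0.30 to 0.011 for miR-125a-5p and -0.18 to 0.66 for miR-99b-5p. Lists ran from -0.35 to 0.11 (miR-17 to 92), -0.13 to 0.036 (hormone response), -0.14 to 0.15 (androgen-responsive), -0.052 to 0.39 (Sfmbt2), -0.44 to 0.088 (HOX-embedded) and -0.25 to 0.038 (miR-29 and miR-30). Without a change of sign, called lists ran from 0.42 to 1.03 (Dlk1-Dio3), 0.32 to 0.97 (erythroid), -0.69 to -0.23 (leukocyte), -1.11 to -0.36 (miR-200) and -0.31 to -0.10 (PCOS). Other lists ran from 0.017 to 0.40 (gonad-enriched), 0.13 to 1.09 (miR-183 cluster), -0.65 to -0.029 (multiciliated), -0.33 to -0.033 (inflammation and hypoxia), -0.49 to -0.22 (smooth muscle), -0.21 to -0.084 (let-7), 0.16 to 0.37 (miR-99, miR-100 and miR-125) and 0.022 to 0.18 (adipose). miR-200a-3p ran from -3.97 to -0.81, miR-130a-3p from -1.75 to -0.62, miR-127-3p from 0.69 to 1.39, miR-3068-3p from -1.42 to -0.81, miR-677-5p from -2.19 to -1.20, miR-184-3p from -2.73 to -1.71, miR-451a from 0.99 to 1.57, miR-155-5p from -1.31 to -0.88 and miR-486a-5p from 1.32 to 1.78. miRNAs of the same name could not be summed, as there were none, and alternatives for normalized values were not needed with counts. Depth limits the low counts: 3 counts are 1.15 RPM in control replicate 6.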

Other observations

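The tests chosen only after the result was seen are both tests of miRNAs on opposite strands, all tests of miRNAs with several loci, the comparison of the Dlk1-Dio3 level between the groups as an explanation, and its correlations with other lists. The miRNA profiles did not sort by group. Across the 368 tested miRNAs, which are not independent replicates, the highest Spearman correlation was between control replicate 3 and PNA replicate 1 (0.973), followed by PNA replicates 2 and 4 (0.965) and by control replicate 2 and PNA replicate 3 (0.960). The median was 0.941 within groups and 0.934 between them. The first principal component held 33.8% of the variance and did not separate the groups (exact permutation p = 0.257), and on the second (28.0%) control replicate 6 stood at 15.1 and the other 6 libraries between -6.52 and 0.72.

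Chance could not be excluded for the count of lists called. Of the 35 splits of the 7 libraries, 8 gave at least the 5 called for the real groups, and the highest other split gave 7. For single miRNAs the splits decide nothing, since a real count of 0 is reached by any split (35 of 35); the highest other split gave 2.

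miRNAs listed on opposite strands of 1 locus held almost the same count in control replicate 6 and in no other library. miR-126a-5p and its antisense partner miR-126b-3p (chromosome 2, overlap 26591363 to 26591420) both had 15984 reads there, while miR-126b-3p had 0 in the other 6 libraries. Independent antisense transcripts would differ at least by sampling noise, yet over the 10 pairs with both arms named and at least 10 reads the sum of squared differences over sums was 0.0303, below the limit set in the lower tail of a chi-square (1.48); the limit to named arms was set after 13 pairs, with 3 names lacking an arm matched to the nearest count, had given 418, nearly all from miR-497b (0 reads against 418 for miR-497a-5p). A candidate explanation that stays open is that reads of this library were counted to both strands, since 10 of the 10 pairs lay within 2 reads there and 0 in the other libraries. Such antisense miRNAs with coordinates in the reference held 0.726% of the library's counts and made up 10 of the 15 miRNAs called without a filter; miR-203b-5p, which has none there and was not tested, had 0 reads in the other 6 libraries and here 139 RPM, the same as miR-203-3p, so both figures are lower bounds, and the high miR-200a-3p and miR-503-5p of this library have no opposite partner and remain without a tested explanation.

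Several miRNAs that are encoded at more than 1 locus had low counts or were not listed. miR-181a-5p averaged 0.0170 RPM while the opposite arms of its hairpins summed to 485 RPM. miR-24-3p was not listed while the opposite arms of its hairpins summed to 99.1 RPM. Many others were not below their opposite arms, among them let-7f-5p (816 RPM) and miR-92a-3p (2731 RPM). If reads aligning to several loci were left out, the shared arm could fall below the sum of its locus-specific opposite arms, although the higher arm of 311 single-locus hairpins exceeded the lower by a median of 9.06 times. This was so in 8 of 18 families with a listed shared arm matched to several annotated loci, under the limit of 0.5 set for the test, and in 10 of 20 when families were formed by name, a definition chosen after the first value was seen, which adds miR-450a-5p and miR-7a-5p and meets the limit; the outcome turns on the definition and stays open, and a further count with 7 unlisted shared arms taken as 0 (17 of 27) decides nothing, as these lie below by construction. Low expression was not decided either, since the median of the highest opposite arm was 1.93 RPM under both definitions, against 0.300 RPM for the lower arm of single-locus hairpins (permutation p = 0.0919 and 0.0805).

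The mean level of the Dlk1-Dio3 list ran from 2.28 to 4.10 log2 CPM between libraries. Scaling shared with other miRNAs of like abundance was argued against, since the SD of 0.73 lay at percentile 100 of 10000 lists matched on mean level, whose median SD was 0.12. Sequencing depth was argued against too, since the SD kept 0.944 of its value after every library was thinned to the lowest total. Prenatal androgen exposure stays open, since the groups overlapped (exact permutation p = 0.229), so that the exposure and differences between single ovaries in cell content or stage, for which no test was set, cannot be told apart. The members varied together, with a median pairwise correlation of 0.680 over the 7 libraries against 0.0176 for all tested miRNAs, and over the same libraries the level correlated with those of many lists, both of blood cells (erythroid 0.890, leukocyte -0.743) and of no single cell type (reported in PCOS -0.968, miR-29 and miR-30 families -0.866, gonad-enriched 0.827, androgen-responsive -0.780), which does not single out an explanation.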
